A study of Mus musculus with 8 samples.

How the data were processed

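Total RNA of mouse aortic tissue was extracted with TRIpure, and libraries were made from 200 ng with the NEBNext Ultra RNA kit, per the labels' protocols. Whether the libraries kept the strand is not given in the sources used here. The submitters' processing notes name bcl2fastq 2.19, fastp 0.23.1, HISAT2 and HTSeq. The same notes name the human builds GRCh38 and hg38, while the gene identifiers of the table are those of mouse (13823 of 13839 occur in GENCODE M21, 13550 with the same symbol). The mouse build the authors used is not given in the sources used here.

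The table deposited by the authors holds, for each gene and library, a raw count of reads and an FPKM value (fragments per kilobase of gene, scaled to the library total), per the file headers. The counts are whole numbers, and each listed gene has a count in at least 3 libraries. Counts that match more than 1 gene are open to loss or splitting: exons of Tagln share 67.9% of their bases with genes on the opposite strand, and its level was 3.75 CPM in control. The results for Tagln, globin, serum amyloid and other genes with near-identical copies or overlaps are therefore uncertain.

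Groups and replicate numbers came from the titles, with 5 controls and 3 TAD libraries. Library totals ran from 12042971 to 15039132 counts. Intervals and floors cover counting error only, since they use counts summed over the libraries of a group and leave out the spread between libraries. Reads were counted without molecular identifiers, so the counting error itself may be understated. A test on log2 FPKM was planned in case only FPKM was given, and the raw counts allowed the planned count test to be used. Counts were filtered with filterByExpr (13701 of 13839 genes kept), scaled with TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) without a covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were the absolute log2 fold change divided by the square root of F. CPM values used TMM-scaled totals, and log2 CPM used a prior count of 2. The biological coefficient of variation was 41.6%. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, over lists of at least 5 tested genes. Lists held 628 genes, of which 585 were in the table and 582 were tested; the other 43 were not analysed here. Exact permutation tests ran over all 56 splits of the libraries into 5 and 3. The list score test was added after the data were examined.

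Named genes were set by a rule before the data were examined: Mex3b and Vcan; the 8 genes with the largest increases and the 8 with the largest decreases among genes with an adjusted p below 0.05, a mean of at least 1 FPKM in the higher group, no overlap between groups and no provisional name; from each list up to 4 called genes with the largest change, and where fewer than 2 were called, the 2 most expressed; and Mex3a to Mex3d. Other names are marked as chosen after their values were seen. A gene that the rule names is not reported here.

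Alternatives were pseudocounts of 0.1 and 0.01, other FPKM filters (none, and a mean of at least 2 in place of 0.5), upper-quartile and quantile scaling, TPM, array weights and no variance trend in limma on log2(FPKM + 1). Further alternatives were DESeq2 1.42.0, an exact rank-sum test, a 2-fold threshold, no count filter, a replicate block, leaving out each library, an estimated correlation and fry. On counts simulated from these libraries with 200 changed genes, edgeR recovered 0% of 50 genes changed 1.5-fold, 14% at 2-fold, 70% at 4-fold and 80% at 8-fold among 13591 genes, and called 5 of 13392 unchanged genes; limma on simulated FPKM recovered 8%, 66% and 72% of the last 3 sizes among 11763 genes. Camera called 5 of 5 simulated lists moved 2-fold and 0 of 35 others among 13593 genes; the simulated genes vary independently, so this says nothing on correlated lists. The 200 changed genes of the edgeR and limma simulation are far fewer than the 3705 genes called in the data. With fewer changed genes the adjustment is stricter, so those shares may understate recovery in this comparison. Exon overlaps and coordinates came from GENCODE M21 on GRCm38.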

Results

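Messenger RNA of mouse aortic tissue was sequenced in 8 libraries, 5 labelled control and 3 labelled TAD. TAD stands here for the thoracic aortic dissection model of the labels. These mice drank beta-aminopropionitrile (BAPN), an inhibitor of the lysyl oxidases that crosslink collagen and elastin, at 1 g/kg per day for 4 weeks from an age of 3 weeks. At 7 weeks they received angiotensin II, a vasoconstrictor peptide, from an osmotic pump at 1 µg/kg per min, and tissue was taken 24 h later. How the control mice were treated is not given in the sources used here. The table held counts for 13839 genes, which summed to between 12042971 (TAD 1) and 15039132 (TAD 3) per library. The labels call the libraries replicates of a group but do not state that each came from a separate mouse, so p-values measure the spread between these libraries.

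The libraries differed within groups as well as between them. The first principal component of log2 CPM (counts scaled to a common library total) held 43.8% of the variance and separated the groups, with scores of 31.5 to 97.2 in TAD and -63.4 to -19.2 in control. The second held 26.8% and ran from control 1 at 72.3 to TAD 3 at -94.0. Pearson correlations across genes were 0.899 to 0.97 between control libraries, 0.83 to 0.895 between TAD libraries and 0.796 to 0.9 across groups. No pair of libraries agreed within sampling noise, since chi-square per gene was at least 48.7. Myh6, a heart muscle myosin gene, ranged from 0.538 CPM (control 5) to 8330 CPM (control 1) among controls and from 0.263 CPM (TAD 3) to 4720 CPM (TAD 1) in TAD. Ckm, a muscle creatine kinase gene, reached 721 CPM in control 2 against 0.384 to 92.5 CPM in the other controls. The neuronal tubulin gene Tubb3 stood at 671 CPM in TAD 2 and at 32.0 CPM or less in TAD 1 and TAD 3. Mitochondrial transcripts took 5.464% to 15.13% of counts in control and 8.103% to 9.563% in TAD. Ckm, Ngfr, Ucp1 and S100a8 were chosen after their values were seen.

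**Figure D1:**
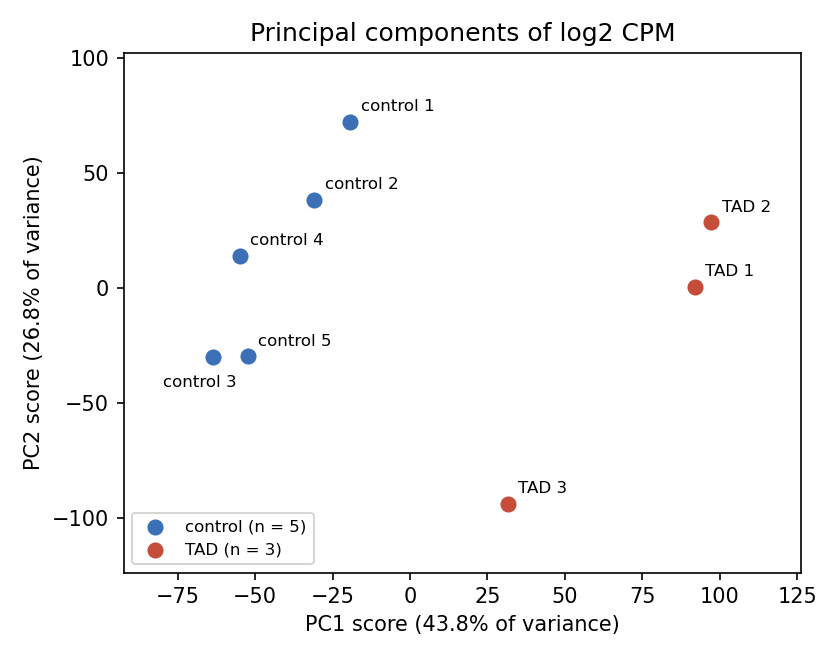
Scores of the 8 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; blue points are control (n = 5) and red points TAD (n = 3). The TAD libraries lie at 31.5 or more on the first component and the controls at -19.2 or less, and TAD 3 lies apart at -94.0 on the second.

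**Figure D2:**
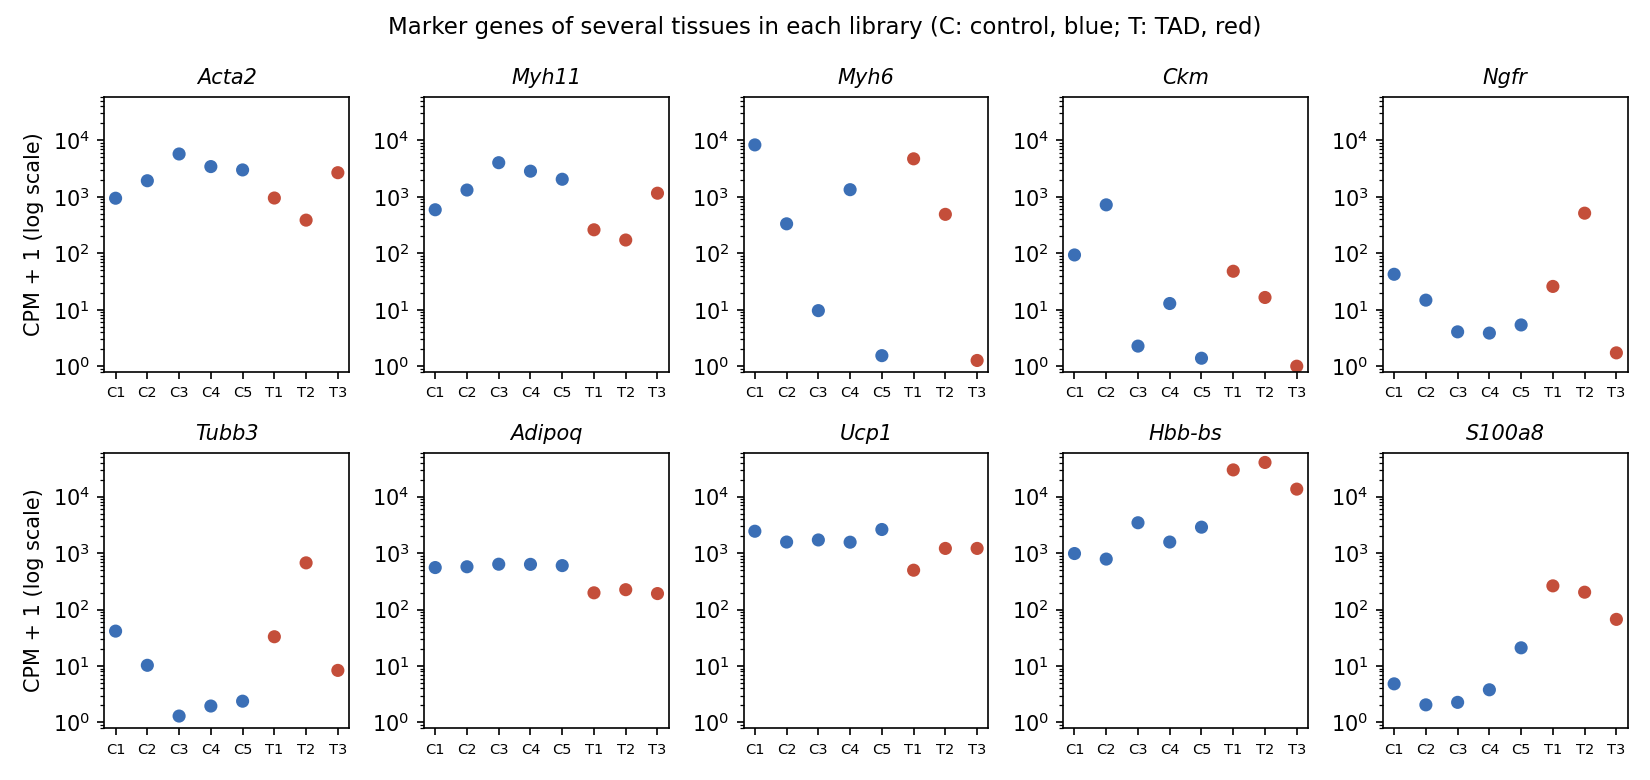
CPM + 1 on a log scale of marker genes for smooth muscle (Acta2, Myh11), heart and skeletal muscle (Myh6, Ckm), nerve (Ngfr, Tubb3), fat (Adipoq, Ucp1), red cells (Hbb-bs) and neutrophils (S100a8) in each library, 1 point per library. Myh6 ranged from 0.263 to 8330 CPM across the libraries of both groups, while Adipoq was 554 to 635 CPM in the 5 controls and 191 to 224 CPM in the 3 TAD libraries.

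The comparison of TAD with control asked which genes differed in the aorta 24 h after the pump. TAD tissue held more mRNA of inflammatory cytokines, of macrophages, neutrophils, platelets and red cells, and of matrix proteases, and less mRNA of adipocyte markers, lipid metabolism and mitochondrial respiration, as lists called by camera at a preset correlation. None of these lists was called with an estimated correlation (adjusted p of 0.218 to 0.461). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3705 of 13701 tested genes were called at an adjusted p below 0.05, 2083 higher and 1622 lower in TAD. Of these, 1145 were at least 2-fold higher and 844 at least 2-fold lower. The groups did not overlap for 4373 genes (31.9%), where chance would give 3.57%. The share of calls that were higher was 56.2%, but it depended on the scaling: limma on log2(FPKM + 1) gave 56.3%, and the same test gave 46.0% after upper-quartile scaling and 36.6% after conversion to TPM. The median log2 fold of the genes in those limma fits was 0.04 with FPKM and -0.13 with TPM, so small changes in either direction are relative to the scaling. Without the heart-rich control 1 and TAD 1, an alternative chosen after seeing the data, 1963 genes were called.

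The study's title links the RNA-binding protein MEX3B to the expression of versican (Vcan), a chondroitin sulfate proteoglycan of the vessel wall. Vcan (ENSMUSG00000021614; GRCm38 chromosome 13, 89655312 to 89742509, minus strand; 16 merged exons) was 3.82-fold higher in TAD, with 75.2 ± 23.4 CPM in control (SD, n = 5) and 287 ± 98.5 CPM in TAD (SD, n = 3). Its log2 fold change was 1.93 ± 0.30 (SE), with an edgeR adjusted p of 0.0028, and each TAD library exceeded each control. The exact two-sided permutation test over the 56 splits of the libraries gave p = 0.0179, the smallest it can give, and 0.0893 after adjustment over the 5 genes tested this way. Mex3b (ENSMUSG00000057706; GRCm38 chromosome 7, 82867333 to 82871515, plus strand; 2 exons) was measured at a low level of 2.87 ± 0.84 CPM in control (SD, n = 5) and 5.82 ± 2.02 CPM in TAD (SD, n = 3), from 22 to 118 counts per library. Its log2 fold change was 1.02 ± 0.36 (SE), and it did not pass the test (edgeR adjusted p = 0.066). The highest control was 3.75 CPM and the lowest TAD library 3.78 CPM, and the exact permutation p was 0.0357 (0.0893 adjusted). These 2 levels rest on 50 counts in control 2 and 46 in TAD 1, so their order lies within counting error. Other tests placed Mex3b on the other side of the threshold, with an adjusted p of 0.0377 by limma on log2(FPKM + 1) and 0.0374 by DESeq2. Within TAD the 2 genes ran in opposite order. Mex3b was 3.78, 7.82 and 5.85 CPM in TAD 1, TAD 2 and TAD 3, and Vcan 391, 195 and 276 CPM. TAD 2, the highest for Mex3b, was also the library with the most Tubb3 (671 CPM). For fibroblast and adventitial markers the mean log2 CPM relative to controls was -1.88 in TAD 2, 0.06 in TAD 1 and 0.33 in TAD 3. The order of Mex3b and Vcan over 3 libraries was not tested. With so few libraries of unlike tissue content it cannot weigh for or against the link in the title. The coordinates are those of GENCODE M21, in which neither gene shares exon bases with another gene.

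Of the other MEX3 genes, Mex3a had a log2 fold change of 1.64 ± 0.53 (edgeR adjusted p = 0.051), Mex3c 0.14 ± 0.20 (adjusted p = 0.66) and Mex3d 0.44 ± 0.23 (adjusted p = 0.20), and none was called by edgeR on all libraries. Mex3a passed without TAD 2 (log2 fold change 2.08, edgeR adjusted p = 0.0061), without control 1, control 2 and TAD 2 (2.17, adjusted p = 0.022), an alternative chosen after seeing the data, and by DESeq2 (1.63, adjusted p = 0.022). In the list of the MEX3 family and other RNA-binding proteins of mRNA stability, 3 of 18 tested genes were higher and 15 were not called. The genes called were Igf2bp2 (1.34 ± 0.36), Zc3h12a (1.07 ± 0.24), an RNase that degrades cytokine mRNAs, and Hnrnpd (0.90 ± 0.15). Igf2bp2 was no longer called without control 2, 3, 4 or 5, TAD 1 or TAD 3, each left out alone (log2 fold changes of 0.98 to 1.35, edgeR adjusted p of 0.0544 to 0.109).

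**Figure D3:**
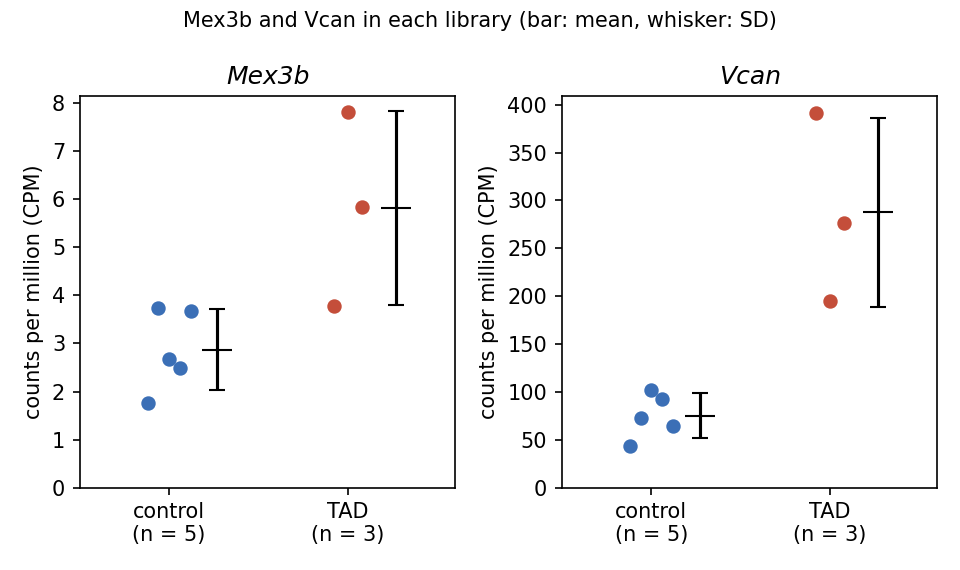
CPM of Mex3b and Vcan in each control (blue, n = 5) and TAD (red, n = 3) library; horizontal marks are means and whiskers SDs. All 3 TAD libraries lie above all 5 controls for both genes. The margin is wide for Vcan (lowest TAD 194.9, highest control 102.1 CPM) and narrow for Mex3b (3.78 and 3.75 CPM). The Mex3b order of TAD 1 (46 counts) and control 2 (50 counts) lies within counting error.

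The genes with the largest increases were chemokine, cytokine and myeloid genes. Cxcl3, a neutrophil chemokine gene, had no count in any control and 5701 counts over the 3 TAD libraries, at least 2950-fold higher over a floor of 3 counts in the control group. Il6 had a log2 fold change of 9.86 ± 1.15 (edgeR adjusted p = 0.00083), with 6 counts over the 5 controls. Cxcl2 (9.72 ± 0.75), Cxcl5 (9.31 ± 0.52), Arg1 (8.99 ± 0.68), the arginase gene of activated macrophages, Spp1 (8.05 ± 0.69), which codes for osteopontin, and Trem1 (7.57 ± 0.88) followed. Cstdc4 had 3 counts in the controls and 518 in TAD, a ratio of 268 with a 95% exact interval of 91.2 to 1300 for counting error. Among the genes with the largest decreases, Olig1 had 164 counts in the controls and none in TAD, at least 35.2-fold lower over a floor of 3 counts in the TAD group. Gdf5 had 228 counts in the controls and 3 in TAD, a ratio of 49.0 with a 95% exact interval of 16.5 to 239 for counting error. Irf4 (-5.14 ± 0.86), Pld6 (-3.98 ± 0.57), Irs3 (-3.85 ± 0.42), an insulin receptor substrate gene of rodent fat, Acsm3 (-3.84 ± 0.45), Dact2 (-3.68 ± 0.65) and Pon1 (-3.60 ± 0.23), a paraoxonase gene, also fell. Exons of Acsm3 and Gdf5 share 39.7% and 40.3% of their bases with genes on the opposite strand, so their counts are uncertain. Leaving out TAD 3 gave 9.03 for Il6, 7.26 for Spp1 and -4.94 for Dact2, leaving out TAD 1 gave 8.99 for Cxcl2, and leaving out control 5 gave 8.94 for Trem1. Il6 had 10.48 without control 1 and 10.45 without control 4. The log2 fold change of Cstdc4 went from 7.89 to 8.84 without control 4 and to 7.12 without TAD 1. That of Gdf5 went from -5.44 to -6.22 without TAD 2. Each of these stayed called.

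Of the 40 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 called 18, 12 higher and 6 lower in TAD. None was called when the correlation between genes was estimated (5 at an unadjusted p below 0.05), and fry called 18, 16 of them the same. The number of called lists does not set the TAD grouping apart, since 23 of the 56 ways to divide the 8 libraries into 5 and 3 called at least 18. A list score is the mean log2 CPM of its members. It differed between the groups for 16 lists in an exact two-sided permutation test (p = 0.0179, adjusted p = 0.0448). All 16 tied at the smallest p this test can give, and the adjusted p passes only because many lists tie. Some lists share members, so these are not separate results. Of the 16 lists, 15 were among the 18. The others of the 18, by adjusted permutation p, were contractile smooth muscle (0.0893), endothelial cells (0.0893) and cell cycle (0.28).

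**Figure D4:**
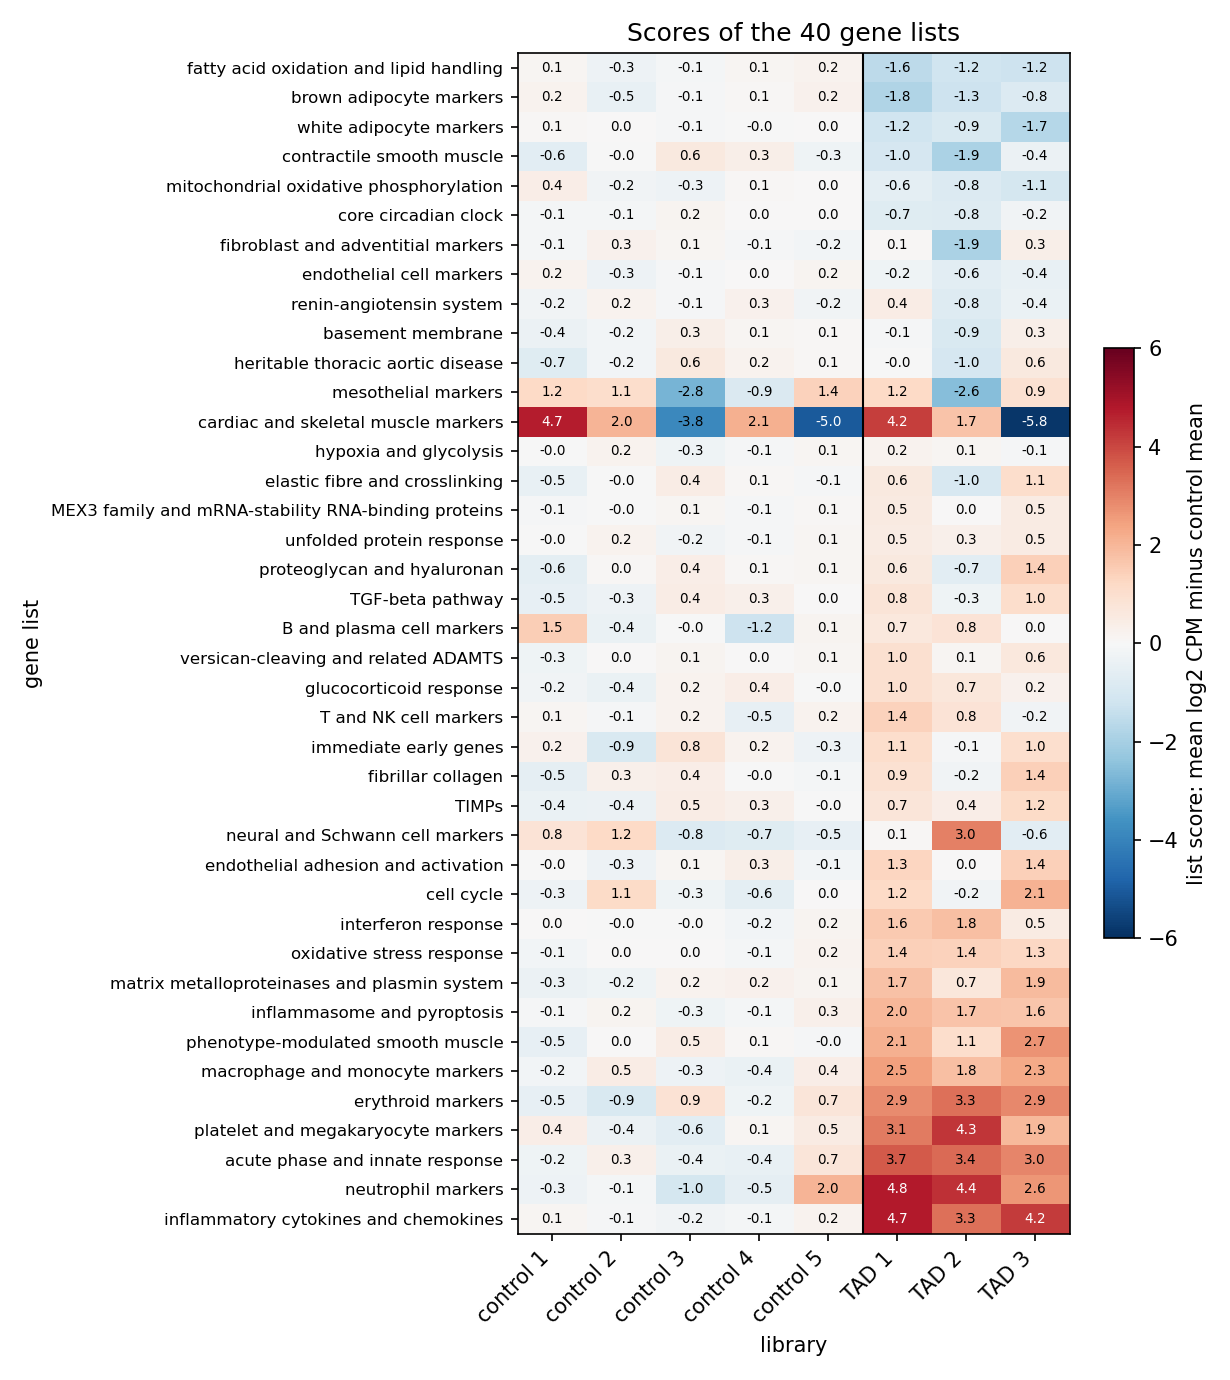
Score of each of the 40 gene lists (rows) in each library (columns), as mean log2 CPM minus the mean of the 5 controls, coloured from -6 (blue) to 6 (red). The cytokine score is 3.29 to 4.74 in TAD and -0.197 to 0.225 in control, while the cardiac and skeletal muscle score varies from -5.83 to 4.73 over the 8 libraries.

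The cytokine list had the highest median log2 fold change of the 40 lists. Of 22 tested cytokines and chemokines, 16 rose and 6 did not pass, with a median log2 fold change of 4.85 that did not move when Cxcl3 was set to its bound (camera adjusted p = 8.68e-10; adjusted p = 0.218 with an estimated correlation). Adjusted over the list alone, 17 passed. Acute phase and innate response genes rose in 11 of 17 (13 adjusted over the list alone; adjusted p = 0.218 with an estimated correlation). They included Lcn2 (7.38 ± 0.87), Ptx3 (7.33 ± 0.78) and Saa3 (6.49 ± 0.77), a serum amyloid gene with close paralogs. Interferon response genes rose in 12 of 20 (12 adjusted over the list alone), with Isg15 at 3.59 ± 0.40, Mx1 at 2.98 ± 0.55 and Irf7 at 2.53 ± 0.35 (adjusted p = 0.461 with an estimated correlation). Inflammasome genes rose in 6 of 10 (7 adjusted over the list alone), among them Il1b (4.92 ± 0.85) and Nlrp3 (4.16 ± 0.44), the sensor of the inflammasome (adjusted p = 0.218 with an estimated correlation). Of 19 oxidative stress genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), and the largest increases were those of Slc7a11 (7.22 ± 0.68), a cystine transporter gene, and Hmox1 (6.31 ± 0.32), which codes for heme oxygenase (adjusted p = 0.235 with an estimated correlation). Ncf4 (3.40 ± 0.34) and Ncf1 (3.31 ± 0.35) of the same list code for subunits of the phagocyte oxidase. Globin transcripts were also higher in each TAD library than in each control. Without TAD 1 Lcn2 had 6.76, Ptx3 6.23 and Saa3 5.54, and without control 5 Lcn2 had 8.23 and Il1b 6.23, all called.

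Of 22 contractile smooth muscle genes, 21 had a negative log2 fold change (median -1.09), but only Synpo2 (-1.98 ± 0.49) and Rgs5 (-1.44 ± 0.33) were called (2 adjusted over the list alone; camera adjusted p = 0.0051; adjusted p = 0.709 with an estimated correlation). Chosen after their values were seen, Acta2 had -1.17 ± 0.72 (edgeR adjusted p = 0.26) and Myh11 -2.03 ± 0.80 (adjusted p = 0.095). Myh11 passed without TAD 3 (log2 fold change -3.33, edgeR adjusted p = 0.0191), with the cardiac marker score as covariate (-2.34, adjusted p = 0.0162), by DESeq2 (-2.04, adjusted p = 0.0099) and by limma after upper-quartile scaling (-2.25, adjusted p = 0.0495). Without TAD 2 the list was no longer called (camera adjusted p = 0.101), and fry did not call it (adjusted p = 0.128). TAD 2, the library with the most Tubb3, had the lowest score of the list (-1.89), and heart-rich control 1 (-0.61) lay below TAD 3 (-0.35). Without TAD 1 Synpo2 had -2.09 (edgeR adjusted p = 0.0563) and Rgs5 -1.31 (adjusted p = 0.0618). Of 20 genes of phenotype-modulated smooth muscle, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with Timp1 at 6.36 ± 0.57, Thbs1 at 4.82 ± 0.52 and Tnfrsf11b at 3.38 ± 0.91 (adjusted p = 0.461 with an estimated correlation). Spp1 and Cd68 of this list are also expressed by macrophages. Of 19 matrix metalloproteinase and plasmin genes 10 rose (10 adjusted over the list alone), among them Mmp8 (4.91 ± 1.16), the urokinase receptor gene Plaur (3.86 ± 0.41) and Mmp9 (3.09 ± 0.58) (adjusted p = 0.461 with an estimated correlation). Mmp8 and Mmp9 are also members of the neutrophil list, so their rise is not specific to the vessel wall. The versican-cleaving protease genes Adamts4 (3.55 ± 0.37) and Adamts5 (0.90 ± 0.22) were called higher, and 8 of the 10 ADAMTS genes were not called. In the proteoglycan and hyaluronan list 5 genes rose and 2 fell of 21. The hyaluronan synthase gene Has1 (4.89 ± 0.82), Tnfaip6 (3.56 ± 0.54) and the hyaluronan receptor gene Cd44 (3.17 ± 0.41) rose, and Hyal1 (-2.02 ± 0.59), whose exons overlap Hyal3, fell. No fibrillar collagen gene of 8 was called, with Col3a1 at 1.10 ± 0.57 and Col1a2 at 0.35 ± 0.64, and Col1a2 turned negative after upper-quartile scaling and conversion to TPM. Without TAD 2 Col3a1 had 1.59 and passed (edgeR adjusted p = 0.0131), and without TAD 3 it had 0.42 (adjusted p = 0.621). Of 21 elastic fibre and crosslinking genes, only Lox (2.50 ± 0.49), which codes for the enzyme that BAPN inhibits, and Loxl4 (1.68 ± 0.53) were called. Some calls were lost with 1 library left out. Without TAD 3 Tnfrsf11b had 1.27 (edgeR adjusted p = 0.178) and Loxl4 0.80 (adjusted p = 0.237). The other losses came with log2 fold changes near those of all libraries. Without control 1, 2 or 5 Tnfrsf11b had 3.17 to 3.31 (adjusted p of 0.0516 to 0.0622), and without TAD 1 or any control Loxl4 had 1.53 to 1.83 (0.0633 to 0.0957). Hyal1 had -2.09 to -1.86 without TAD 1 or without control 2, 3, 4 or 5 (0.0549 to 0.117). Hyal1 had -2.94 without TAD 3 and stayed called. Mmp8 had 6.66 and Mmp9 3.79 without control 5, Adamts4 had 2.94 without TAD 1 and Has1 4.04 without TAD 3, all called. Without TAD 1 Mmp8 had 4.31 (0.0575) and Adamts5 0.79 (0.0742), and without TAD 3 Adamts5 had 0.73 (0.057). Without control 1, control 2 and TAD 2, an alternative chosen after seeing the data, Mmp8 had 4.35 and Mmp9 2.68. Both were then no longer called (edgeR adjusted p of 0.0927 and 0.0512).

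All 22 tested oxidative phosphorylation genes had negative log2 fold changes and 14 were called lower (15 adjusted over the list alone), among them Sdha (-1.22 ± 0.18), Sdhb (-1.14 ± 0.24) and Ndufb8 (-1.12 ± 0.21) (camera adjusted p = 1.17e-07; adjusted p = 0.461 with an estimated correlation). Of 22 genes of fatty acid oxidation and lipid handling, 16 fell and 1 rose (16 and 1 adjusted over the list alone). Dgat2 (-3.57 ± 0.25), an enzyme of triglyceride synthesis, fell 11.9-fold, Ppara (-3.13 ± 0.28) fell 8.74-fold, and the fatty acid synthesis genes Fasn (-2.68 ± 0.81) and Acaca (-1.98 ± 0.56) also fell (adjusted p = 0.368 with an estimated correlation). Fasn was no longer called without any single library other than TAD 3 (log2 fold changes of -2.81 to -2.20, edgeR adjusted p of 0.0512 to 0.0968), nor was Acaca without TAD 1, TAD 2 or any of controls 2 to 5 (-2.02 to -1.56, adjusted p of 0.0526 to 0.0827). Without TAD 3 Fasn had -4.35 and Acaca -2.79, both called. White adipocyte markers fell in 8 of 12 genes (10 adjusted over the list alone), with Car3 at -2.79 ± 0.23 and Adipoq, the adiponectin gene, at -1.55 ± 0.14 (adjusted p = 0.235 with an estimated correlation). Brown adipocyte markers fell in 8 of 13 (9 adjusted over the list alone), with Cidea at -2.25 ± 0.37 and Kcnk3 at -1.96 ± 0.26 (adjusted p = 0.388 with an estimated correlation).

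Of 21 macrophage and monocyte genes 11 rose (12 adjusted over the list alone), among them Chil3 (5.82 ± 0.92), Fcgr1 (4.45 ± 0.37) and the integrin gene Itgam (4.44 ± 0.47), which shares 68.7% of its exon bases with a read-through gene model (adjusted p = 0.388 with an estimated correlation). Of 17 neutrophil genes 11 rose (12 adjusted over the list alone), with Retnlg at 6.28 ± 1.26 and Wfdc21 at 5.77 ± 0.75 (adjusted p = 0.461 with an estimated correlation). Of 10 platelet genes 9 rose (10 adjusted over the list alone), with Clec1b at 4.13 ± 0.55 and Ppbp at 3.78 ± 0.47 (adjusted p = 0.437 with an estimated correlation). Of 10 erythroid genes 8 rose (9 adjusted over the list alone), with Hbb-bs at 3.85 ± 0.58 and Alas2, an enzyme of heme synthesis, at 3.62 ± 0.61 (adjusted p = 0.388 with an estimated correlation). Without control 5 Retnlg had 7.83 and Chil3 6.93, without TAD 1 Retnlg had 5.59 and Wfdc21 5.04, and without TAD 2 Chil3 had 5.15, Clec1b 3.24 and Ppbp 3.16, all called. Retnlg was lost without control 1 and TAD 1 (edgeR adjusted p = 0.0596) and without control 1, control 2 and TAD 2 (0.0545), alternatives chosen after seeing the data. Globin genes took 3.04% to 7.8% of counts in the TAD libraries and 0.163% to 0.705% in the controls, and these genes are near-identical copies whose reads the counting could split. Endothelial markers fell in 5 of 14 genes (6 adjusted over the list alone), with Kdr at -1.30 ± 0.21 and Tek at -0.79 ± 0.12 (camera adjusted p = 0.0107; adjusted p = 0.644 with an estimated correlation), and the list was no longer called without TAD 2 (camera adjusted p = 0.0721). Endothelial activation genes Sele (3.55 ± 0.78), Selp (2.94 ± 0.40), Vcam1 (2.36 ± 0.56) and Edn1 (1.52 ± 0.25) rose, and 6 of the 10 in that list were not called (camera adjusted p = 0.259). Selp had 2.27 without TAD 1 and stayed called, and Vcam1 was lost without TAD 3 (log2 fold change 1.52, edgeR adjusted p = 0.0558). Sele (3.36, edgeR adjusted p = 0.0656) and Vcam1 (2.37, adjusted p = 0.0774) were lost without control 1 and TAD 1. Cell cycle genes had positive log2 fold changes in all 24, of which 4 were called (4 adjusted over the list alone), with Ccne1 at 1.72 ± 0.35 (camera adjusted p = 0.0022; adjusted p = 0.73 with an estimated correlation), and the list was no longer called without TAD 3 (camera adjusted p = 0.13).

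The remaining lists were not called by camera. The unfolded protein response list came nearest (adjusted p = 0.0515), with Atf4 at 1.02 ± 0.16 and Manf at 1.05 ± 0.18 among its 4 higher genes, and it passed without control 2 (0.0288), control 5 (0.0377) or TAD 2 (0.0442) and by fry (0.0145). Immediate early genes (adjusted p = 0.121) included Fosl1 (5.22 ± 0.97), Ier3 (2.83 ± 0.44) and Myc (2.62 ± 0.31) among 4 higher genes, and the list passed without control 3 (0.0302) or TAD 2 (0.011). Fosl1 had 6.04 without control 5 and stayed called. The circadian clock list (adjusted p = 0.15) held Hlf (-2.22 ± 0.22) and Cry2 (-1.02 ± 0.26), which fell, and Nfil3 (1.62 ± 0.24), which rose. Cry2 was lost without TAD 1 (-0.81) or without TAD 3 (-0.98), with an edgeR adjusted p of 0.0548 in both. The score of the list was lower in TAD by the exact permutation test (adjusted p = 0.0448), and fry called the list (adjusted p = 0.000908). Glucocorticoid response genes (adjusted p = 0.216) included Fkbp5 (2.17 ± 0.42) and Cebpd (2.10 ± 0.33). Camera adjusted p was 0.16 for T and NK cells, 0.278 for the MEX3 family list, 0.323 for fibroblasts, 0.332 for ADAMTS, 0.337 for fibrillar collagen, 0.337 for the TGF-beta pathway, 0.405 for B and plasma cells and 0.445 for the renin-angiotensin system. It was 0.59 for proteoglycan and hyaluronan, 0.651 for basement membrane, 0.701 for neural and Schwann cells, 0.725 for genes of heritable thoracic aortic disease, 0.759 for elastic fibres, 0.861 for hypoxia and glycolysis and 0.97 for each of TIMPs, mesothelial markers and cardiac and skeletal muscle. The TIMP list had a negative median (-0.35), a positive mean (0.95) and a downward camera direction, and Timp1 was its only called member. The heritable disease list had a median of 0.17 and a mean of -0.03, the renin-angiotensin list a median of -0.01 and a mean of 0.04, and the hypoxia list a positive median (0.13) and mean (0.11) with a downward camera direction. The cardiac and mesothelial lists had a downward direction by camera and an upward one by fry. Without TAD 2 the lists of fibrillar collagen (camera adjusted p = 0.0402), elastic fibres (0.0146), the TGF-beta pathway (0.0402), endothelial adhesion (0.0131) and the MEX3 family (0.041) passed the threshold, each upward. Without TAD 3 the T and NK cell list passed, upward (0.0174).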

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

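The tests of causes in these paragraphs were chosen after the results were seen. Among 189 values checked in the 5 controls (levels of named genes, list scores, library totals and shares), 13 had 1 library set apart from the others, where about 9.45 would be expected by chance at 1 in 20. The check was first run on 64 of these values, without the list members named by the rule, and 0 of those stood out; it was widened after that result was seen. In control 5, 7 genes were far above the other controls: Mmp8 (3.53 CPM), Mmp9 (32.1), Lcn2 (8.29), Il1b (9.6), Chil3 (7.91), Retnlg (5.14) and Fasn (28100). All but Fasn are genes of neutrophils or other myeloid cells. Control 1 stood apart in Myh6 (8330 CPM), Actc1 (2820), Tubb3 (40.5), Jchain (44.5) and Tef (137, below the others), and control 2 in Cd44 (66.9).

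The first pattern is the lower contractile smooth muscle list in TAD. Heart or skeletal muscle in the pieces was argued against as the whole cause, since the mean cardiac marker score of TAD was only 0.0109 relative to control. The score varied widely within groups (SD 4.22 in control, 5.2 in TAD). With it as a covariate the median log2 fold of the list was -1.24 (median SE 0.467). The list stayed called (camera adjusted p = 0.000766 at the preset correlation). A score so alike in group mean could hardly have moved the fold, so the covariate fit adds little. Whether a lower share of aortic wall muscle was the whole cause was not decided. The macrophage score minus the endothelial score rose by 2.61 (SD within groups 0.426, exact permutation p = 0.0179). That difference holds no smooth muscle gene, and macrophages added to the pieces would raise it while lowering the muscle share, so it cannot decide. The weight of TAD 2, the library with the most nerve transcripts, cannot be told apart from a group difference. Without it the adjusted p was 0.101 and the median -0.771, with 19 members still negative, and 2 TAD libraries remain. A change in the muscle cells with the TAD treatment, the biological explanation, stays open and was not tested.

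The second pattern is the rise of red cell, platelet and neutrophil markers in TAD. Blood of one composition in the pieces could account for these lists: the neutrophil score minus the erythroid score differed by 0.916 between the groups, less than the SD of 1.18 within groups (exact permutation p = 0.357), and the platelet score minus the erythroid score by 0.105 (SD 0.946, exact permutation p = 0.929). With 3 TAD libraries these tests would miss a moderate gain of neutrophils, so recruited cells stay open, and bleeding into the wall is itself part of the model. Cytokine genes such as Il6 were not part of this test.

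The third pattern is the fall of lipid synthesis genes beside that of adipocyte markers. A smaller share of fat in the TAD pieces remains possible: the score of 20 lipogenic genes minus the white adipocyte score was lower by 0.778 in TAD, just above the SD of 0.694 within groups, with an exact permutation p of 0.143. The test decided neither way, and a change in the fat cells themselves stays open as the biological explanation.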

How the results depend on the processing

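The alternatives that use the cardiac marker score or leave out several libraries were chosen after the data were seen. The causes of the changes listed here were not tested, apart from those set by the alternative itself. No called gene among the 128 named genes with a call reversed under a left-out library; 32 lost the call in at least 1 of these fits and 96 kept it. Of the same 128, 34 lost it without control 1 and TAD 1, 18 without control 1, control 2 and TAD 2, 16 with TPM and 1 with the cardiac score as covariate. The fold of 35 of the 128 moved by over 1.5 times when a single library was left out. With single libraries left out, edgeR called 2549 to 3728 genes, 1408 to 2076 higher and 1141 to 1660 lower, and 18 to 23 lists. Mex3b then had log2 fold changes of 0.74 to 1.23 and Vcan of 1.64 to 2.15. Vcan stayed called in 25 of 26 alternatives, and the exception was the exact rank-sum test, which called no gene. Mex3b stayed uncalled in 19 of 25, among them the exact rank-sum test, and has no value under the stricter FPKM filter. The smallest p of the rank-sum test passes the adjustment only when most tested genes reach it, so its result says little on either gene. Counts of 22 to 118 limit the precision for Mex3b.

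Whether replicate numbers pair the samples was not settled: deviations of same-numbered libraries correlated at 0.427, 0.0972 and 0.544. TAD 1 correlated best with control 1 (0.427) and TAD 3 with control 3 (0.544), while TAD 2 correlated best with control 1 (0.362). The cardiac and skeletal muscle score was high in control 1 (4.73) and TAD 1 (4.15). It was low in control 3 (-3.85), control 5 (-5.04) and TAD 3 (-5.83). The correlations of 0.427 and 0.544 therefore cannot be told apart from likeness in heart muscle content. TAD 2 (1.70) was nearest in this score to control 2 (2.03), yet correlated with it at only 0.0972. With the replicate block edgeR called 1255 genes (672 higher, 583 lower) and limma 1170 (673 higher, 497 lower), and 45 of the 128 named calls were lost by edgeR; Actc1 had -1.87 by edgeR and -1.36 by limma, and Timp3 0.022 by limma. Controls 4 and 5 have no TAD library of the same number, so under the block they add nothing to the group difference. The block also fits a term per replicate number, which leaves less to estimate the spread from. Part of the loss of calls is thus set by the design. The block gave camera adjusted p of 0.816 for both the hypoxia and the mesothelial lists, with directions turned.

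Without the heart-rich control 1 and TAD 1, 1963 genes were called (1098 higher, 865 lower), Actc1 had -1.57 and Msln -0.44, and the elastic fibre list turned (0.755). Without control 1, control 2 and TAD 2, Myh6 had 2.38, and the lists of heritable disease (0.868), fibroblasts (0.24), cardiac and skeletal muscle (0.687) and mesothelial markers (0.0947) turned. With the cardiac score as covariate Actc1 had -1.04 and the cardiac list turned (0.893).

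A 2-fold threshold left 1989 genes (1145 higher, 844 lower). The exact rank-sum test called 0 genes in total, 0 higher and 0 lower, with 4373 at an unadjusted p below 0.05, where 0.0357 is the smallest p the test can give; Vcan there had 1.93 and an adjusted p of 0.112. Camera with an estimated correlation called 0 lists, with 5 at an unadjusted p below 0.05.

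Mex3b passed the threshold at 0.56 by limma on log2(FPKM + 1), also without the FPKM filter or the variance trend, at 0.96 and 1.03 with pseudocounts of 0.1 and 0.01, and at 1.01 by DESeq2. Calls were also gained by Mex3a in 3 alternatives, Myh11 in 6, Tubb3 in 4 and Col3a1 in 2, and by the unfolded protein response list in 7 and immediate early genes in 4. Under the block Myh11 passed by edgeR (adjusted p = 0.0474) and limma (0.0472). After conversion to TPM 943 genes were called higher. Myh6 turned to 0.30 by limma with each FPKM filter and without the trend, 0.10 with a pseudocount of 0.1, 0.26 after upper-quartile scaling, 0.33 after quantile normalization, 0.030 with TPM and 1.71 with array weights. Actc1 turned to -0.46 by limma with each FPKM filter and without the trend, -1.38 and -2.47 with pseudocounts of 0.1 and 0.01, -0.53 after upper-quartile scaling, -0.64 after quantile normalization and -1.21 with TPM. Col1a2 turned to -0.012 after upper-quartile scaling and -0.10 with TPM. Ace turned to -0.061 after upper-quartile scaling, -0.062 after quantile normalization and -0.16 with TPM, and Mex3c to -0.016 with TPM. Lists that turned, by adjusted p after upper-quartile scaling, quantile normalization and TPM in this order, were TIMPs (0.978, 0.952, 0.821), cardiac and skeletal muscle (0.802, 0.81, 0.634) and mesothelial markers (0.944, 0.966, 0.821); by fry these were 0.37, 0.984 and 0.972.

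Some uncalled results turned when single libraries were left out. The log2 fold changes ranged from -3.05 to 2.05 for Myh6, -2.85 to 1.30 for Actc1, -0.68 to 0.26 for Timp3, -0.61 to 0.50 for Msln, -0.37 to 0.83 for Col1a2, -0.57 to 0.53 for Ace and -0.024 to 0.28 for Mex3c. The adjusted p of lists that turned ranged from 0.0146 to 0.987 for elastic fibres, 0.195 to 0.771 for basement membrane, 0.0737 to 0.74 for proteoglycans, 0.62 to 0.988 for TIMPs, 0.212 to 0.901 for heritable disease, 0.599 to 0.988 for hypoxia, 0.0525 to 0.431 for fibroblasts, 0.299 to 0.904 for cardiac and skeletal muscle, 0.329 to 0.822 for neural cells and 0.263 to 0.904 for mesothelial markers.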

Other observations

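The lists of lipogenesis, fasting and ganglion genes and the fasting test were chosen after some of their members had been seen. Lipid synthesis genes fell widely: of 20 genes of de novo lipogenesis, 15 were lower in TAD, none was higher and 5 were not called (median log2 fold change -1.73, exact permutation p = 0.0179 for the score). Thrsp, a regulator of lipogenesis, fell by 3.35 on the log2 scale, Acly by 2.13 and Acacb by 2.31, whereas Scd1, the most abundant of them, had -0.91 (edgeR adjusted p = 0.15). Genes of sympathetic ganglia were concentrated in TAD 2: Ngfr was 513 CPM there against 0.723 to 41.5 CPM elsewhere, Gap43 180 CPM, Prph 552 CPM and Npy 145 CPM. None of the 8 tested ganglion genes was called between the groups by edgeR on all libraries. Tubb3 was called without control 1 (log2 fold change 6.31, edgeR adjusted p = 0.0385), with the cardiac marker score as covariate (5.18, adjusted p = 0.0191), by DESeq2 (4.5, adjusted p = 0.0281) and without control 1, control 2 and TAD 2 (4.45, adjusted p = 0.0161). Over the 8 genes the mean log2 CPM relative to controls was 7.22 in TAD 2, 3.11 in TAD 1 and -0.97 in TAD 3, beside 3.39 in control 1, 1.17 in control 2 and -2.1 to -0.924 in the other controls. Of the 16 genes of this list, 6 are also in the fixed lists.

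A fasting-like state of the TAD mice may be asked about, since lipogenic genes respond to feeding. The score of 15 fasting-induced genes differed by -0.302 between TAD and control (SD within groups 0.422, exact permutation p = 0.393), with 3 genes higher, 5 lower and 7 not called. Ddit4 (2.05) and Cdkn1a (1.52) rose and Ucp3 (-1.42) and Pnpla2 (-1.02) fell, so this test gave no decision on the hypothesis.

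The number of called genes was tested on all 56 ways to divide the 8 libraries into 5 and 3, in a test fixed before its result was seen. The TAD grouping was the only 1 that reached its 3705 genes, and likewise its 2083 higher and its 1622 lower genes. With 56 splits the smallest share such a test can give is 0.0179, so chance was argued against for these counts but not excluded. Every other split puts TAD and control libraries together in a group, which can widen the spread within groups and lower its count. The highest count of the other splits by edgeR was 0, with up to 2000 genes at an unadjusted p below 0.05, up to 6 by limma on log2(FPKM + 1) and up to 685 by DESeq2; the counts by limma and DESeq2 were added after the edgeR counts were seen. For gene lists the number called did not set the TAD grouping apart: 23 of the 56 splits called at least the real 18 lists, and the highest other split called 30.

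Rows of the deposited table form 3 runs, each sorted by identifier. All 1461 genes of the first run had a higher mean FPKM in TAD, and 1126 of them were called higher. The run holds Vcan, which was called, and Mex3b, which was not. None of the 1199 genes of the second run had a higher mean FPKM in TAD, and 867 were called lower. The remaining 11179 genes held 957 called higher and 755 called lower. The table does not say what the runs are.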
